A study of Rattus norvegicus with 9 samples.

How the data were processed

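Gene expression was measured by bulk RNA sequencing in 9 libraries of rat (S-D strain) hypothalamic tissue that held the supraoptic nucleus and the paraventricular nucleus, the regions with the magnocellular neurons that make vasopressin and oxytocin. Per the labels' protocols, the tissue was frozen, total RNA was extracted with Trizol and libraries were sequenced on the Illumina NovaSeq platform. Per the submitters' processing notes, the tools used were HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.16.1. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Whether reads of overlapping or antisense genes, and of near-identical gene copies, were told apart in these values is therefore not known.

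The authors deposited 1 table of raw whole-number counts per gene, with no normalization, and it had 34784 rows. Of these, 32883 had Ensembl rat gene IDs and 1901 had IDs of another form, outside Ensembl's naming. No row was a total or an unassigned class. The table did not pair IDs with symbols, and the rat gene table used here, with 47357 rows, held an Ensembl ID in 0 of them, so 0 IDs were matched to a symbol. For this reason 37 gene lists fixed before the data were examined were not tested. Atf3, Jun, Lgals3, Avp and Oxt, which were to be named in any case, could not be picked out among the IDs. A gene given here only by ID may be among them. Genes were grouped instead by their course over time and by their abundance, a choice made after the data were seen.

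Libraries were assigned to Control, 1 d after PEL surgery or 7 d after PEL surgery by their titles, with 3 libraries each. Genes were kept by edgeR's filterByExpr function with default settings, which left 17345 genes for testing, 1574 of them with IDs outside Ensembl's naming. The 17439 rows left out, of which 9788 had no count in any library, held between 0.0670 and 0.0972% of the counts of a library. Counts were scaled by TMM factors and tested with edgeR's quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) in 1 fit of all 9 libraries with group as the only term. The common biological coefficient of variation was 0.189. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and a gene was called changed at an adjusted p below 0.05. Standard errors of log2 fold changes were taken as the size of the log2 fold change divided by the square root of the F statistic. CPM values were computed on TMM-scaled library sizes, and log2 CPM values used a prior count of 2. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

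The rule for genes given by name was fixed before the data were examined. It took, for each comparison with Control, the 6 largest rises and the 6 largest falls among genes with a symbol, an adjusted p below 0.05, a mean of at least 5 CPM in the higher group and all 3 libraries of a group above all 3 of the other. Because no symbol was matched, the rule was applied without its symbol condition, the single largest rise and fall of each comparison with Control were given by ID, and the 6 largest were summarised. No ID was printed by the rule for 7 d against 1 d.

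Total counts ranged from 13338433 to 21012998 per library. On counts simulated from these libraries with 200 changed genes, the test recovered 31.3% of 1.5-fold, 70.1% of 2-fold and 89.4% of 4-fold changes for 1 d against Control (17173 genes tested, 8 false calls). For 7 d against Control the recovered shares were 26.9%, 56.7% and 92.4% (17168 genes, 17 false calls). For 7 d against 1 d they were 32.8%, 56.7% and 78.8% (17150 genes, 9 false calls). Counting intervals of count ratios were exact 95% intervals, which cover counting error only. Replicate libraries were compared by a chi-square test of their counts; the statistic divided by its degrees of freedom lay between 7.18 and 40.5 in the 9 pairs, so no pair agreed within sampling noise and none was taken as a repeat of the same library.

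Both comparisons with Control used the same Control libraries. The overlap of their calls was therefore set beside the overlap of independent lists and beside 50 simulations of unchanged groups against the same controls. Group separation was measured as a pseudo-F statistic on distances of log2 CPM, with all partitions enumerated. Shares of counts were compared by exact two-sided permutation tests, which cannot give a p below 0.1 with 3 libraries against 3. Alternatives planned before the data were examined were DESeq2 size factors, upper-quartile factors and library totals as scaling, no filter on low counts, a filter of more than 1 CPM in at least 3 libraries, DESeq2, limma-voom, fits of only the compared groups, replicate number as a block, a 2-fold minimum and leaving out each library in turn. Alternatives added after the data were seen were thinning all libraries to 13338433 counts, Ensembl IDs only, removal of the 20 most abundant genes, cyclic loess normalization, shares of counts over 10 and 100 genes, the pseudo-F with DESeq2 size factors and with the filter on CPM, and, for the shares of counts and the pseudo-F, leaving out each library in turn. The comparison of calls between abundance classes, with all its settings, was also chosen after the data were seen.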

Results

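The transcriptome of rat hypothalamic tissue that held the supraoptic and paraventricular nuclei was measured by bulk RNA sequencing. There were 3 Control libraries, 3 libraries taken 1 d after PEL surgery and 3 taken 7 d after it. In bulk tissue a change can come from any of its cells. The labels do not spell out PEL; in the published study it is a pituitary stalk electrical lesion, which damages the axons that carry vasopressin and oxytocin from these nuclei to the posterior pituitary. The series asks how hypothalamic injury changes gene expression in a model of central diabetes insipidus, the failure to concentrate urine when vasopressin is lacking. The labels do not say what treatment the Control animals had, and do not state that each library came from a separate animal, so p-values measure the spread between these libraries. Total counts per library ranged from 18948576 to 21012998 in Control, from 13338433 to 17294334 at 1 d and from 17014260 to 18685921 at 7 d. The 1 d libraries were all shallower than the Control libraries (exact permutation p = 0.1, the smallest that 3 against 3 can give). The files do not pair gene IDs with symbols, so genes are described by their time course and abundance, and 4 are given by ID.

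Over all 17345 tested genes the 3 groups were not all alike. The real grouping had the highest pseudo-F, 2.69, of the 280 partitions of the libraries into groups of 3 (exact permutation p = 0.00357, the smallest possible). The mean distance between libraries was 93.7 between Control and 1 d and 93.5 between 1 d and 7 d, against 78.8 between Control and 7 d. Control libraries lay 80.1 apart on average, farther than the 66.7 within 1 d and the 65.7 within 7 d. On average they thus lay slightly farther from each other than from the 7 d libraries, but the ranges overlapped. The 3 pairs of Control libraries lay 67.8 to 91.1 apart, and the 9 pairs of a Control and a 7 d library 73.0 to 88.4. Taken by pairs, the pseudo-F was 2.89 for 1 d against Control, 1.46 for 7 d against Control and 3.97 for 7 d against 1 d, each with an exact permutation p of 0.1, the smallest that 3 against 3 can give.

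**Figure D1:**
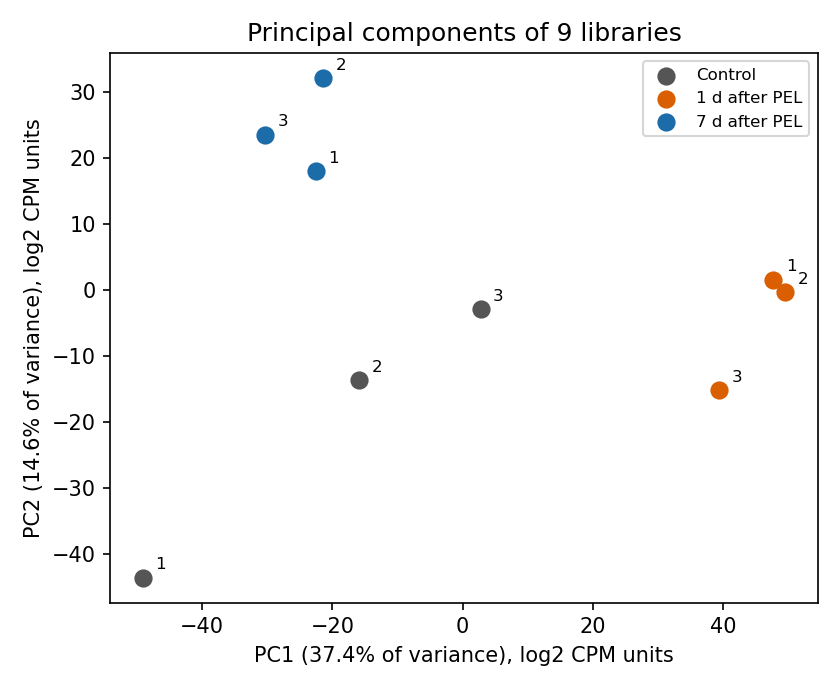
Principal components of log2 CPM of the 9 libraries, with component 1 (37.4% of variance) on the x axis and component 2 (14.6%) on the y axis; each point is a library, numbered by replicate and coloured by group. The 1 d libraries lie at 39.3 to 49.6 on component 1 and all others at 2.75 or below, while Control replicate 1 lies apart at -49.1 and -43.5.

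The first comparison asked which genes had changed 1 d after surgery. At that time 1977 genes were higher and 1563 lower than in Control (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05), 20.4% of the genes tested. Rises were larger than falls. The median log2 fold change was 0.79 among the genes that rose, a 1.72-fold increase, and -0.39 among those that fell, a ratio of 0.763. At least 2-fold changes numbered 700 upward and 43 downward, and at least 4-fold changes 149 upward and 12 downward. Genes that fell were the more abundant, with a median of 64.0 CPM against 17.8 CPM for genes that rose and 17.1 CPM for all tested genes. With library totals as the only scaling the split moved to 2471 higher and 856 lower. The number of calls was 1577 without Control replicate 2, 1575 without 1 d replicate 1, 1440 without 1 d replicate 2 and 2066 in a fit of Control and 1 d alone.

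Among genes that met the naming rule, the 6 with the largest rises at 1 d had increased 16.1- to 33.6-fold, and the 6 with the largest falls had decreased 2.24- to 9.45-fold. The largest rise was that of ENSRNOG00000058105, from 1.71 ± 0.771 CPM in Control to 57.2 ± 14.9 CPM at 1 d (SD, n = 3 each), a log2 fold change of 5.07 (SE 0.715, edgeR adjusted p = 0.00662). At 7 d this gene was at 1.96 ± 1.87 CPM, which differed from Control by a log2 fold change of 0.22 (adjusted p = 0.951) and from 1 d by -4.86 (adjusted p = 0.00357). The largest fall was that of ENSRNOG00000005017, from 7.76 ± 1.42 CPM to 0.835 ± 0.545 CPM, a log2 fold change of -3.24 (SE 0.418, edgeR adjusted p = 0.00336). It stood at 7.31 ± 0.282 CPM at 7 d, with a log2 fold change of -0.09 from Control (adjusted p = 0.956) and 3.15 from 1 d (adjusted p = 0.00121). In both genes all 3 libraries of 1 d lay outside the range of the other 6. Of the 6 largest rises 4 had fallen again by 7 d in the direct test, and of the 6 largest falls 4 had risen again.

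The second comparison asked what remained or had appeared by 7 d. At 7 d 146 genes were higher and 31 lower than in Control (edgeR, adjusted p below 0.05), 1.02% of the genes tested. The genes that rose did so by a median log2 fold change of 1.01, a 2.01-fold increase, and those that fell by a median of -0.74, a ratio of 0.599. At least 4-fold changes numbered 26 upward and 0 downward. An unadjusted p below 0.05 was found for 2136 genes. The number of genes called at 7 d, 177, moved by more than 1.5 times whichever library was left out: it was 739 without Control replicate 1 (340 higher, 399 lower), 7 without Control replicate 2 and 98 without Control replicate 3. It was 91, 107 and 105 without 1 d replicates 1, 2 and 3, and 41, 27 and 113 without 7 d replicates 1, 2 and 3. DESeq2 called 514 genes, which included all 177 of the genes called here, and a fit of Control and 7 d alone called 28.

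The 6 largest rises at 7 d were 9.46- to 236-fold, and all 6 genes had also risen at 1 d; the highest of these folds is a fitted value that depends on the prior count. The largest was that of ENSRNOG00000024028, which had 2 counts in the 3 Control libraries together, 216 at 1 d and 505 at 7 d. Its mean was 4.34 ± 2.60 CPM at 1 d and 9.69 ± 5.82 CPM at 7 d (SD, n = 3 each), against 0.0349 ± 0.0605 CPM in Control. The ratio of its depth-scaled counts to Control was 133 at 1 d (95% counting interval 36.4 to 1105) and 283 at 7 d (77.8 to 2340). Both Control counts were in Control replicate 1, and without that library the fitted log2 fold change moved from 7.88 to 10.41, against controls at 0. Its edgeR adjusted p was 0.00623 at 1 d and 0.0157 at 7 d, and the log2 difference of 1.15 between the times was not called (adjusted p = 0.189). Its 7 d call was lost in 7 of 22 alternatives (adjusted p 9.96e-10 to 0.122 over all of them), 4 of which left out Control replicate 2 or 3 or 7 d replicate 1 or 2.

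The 6 largest falls at 7 d were 1.92- to 3.21-fold, and all 6 genes were also lower at 7 d than at 1 d. The largest was that of ENSRNOG00000021229, an abundant transcript at 1481 ± 384 CPM in Control, 2438 ± 712 CPM at 1 d and 461 ± 97.2 CPM at 7 d (SD, n = 3 each). At 7 d it was 3.21-fold lower than Control (log2 fold change -1.68, SE 0.282, edgeR adjusted p = 0.0409) and 5.28-fold lower than at 1 d (log2 fold change -2.40, SE 0.289, adjusted p = 0.00155). At 1 d it differed from Control by a log2 fold change of 0.72 that was not called (SE 0.275, adjusted p = 0.103); it was called without 1 d replicate 3 (0.94, adjusted p = 0.0365) and after cyclic loess normalization (0.91, adjusted p = 0.0467), with adjusted p up to 0.257 over 22 alternatives. Its 7 d call was lost in 11 of 22 alternatives (adjusted p 1.00e-05 to 0.133), 8 of which left out a library, namely any library other than 1 d replicate 3. The difference between 7 d and 1 d was called in all 22.

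**Figure D2:**
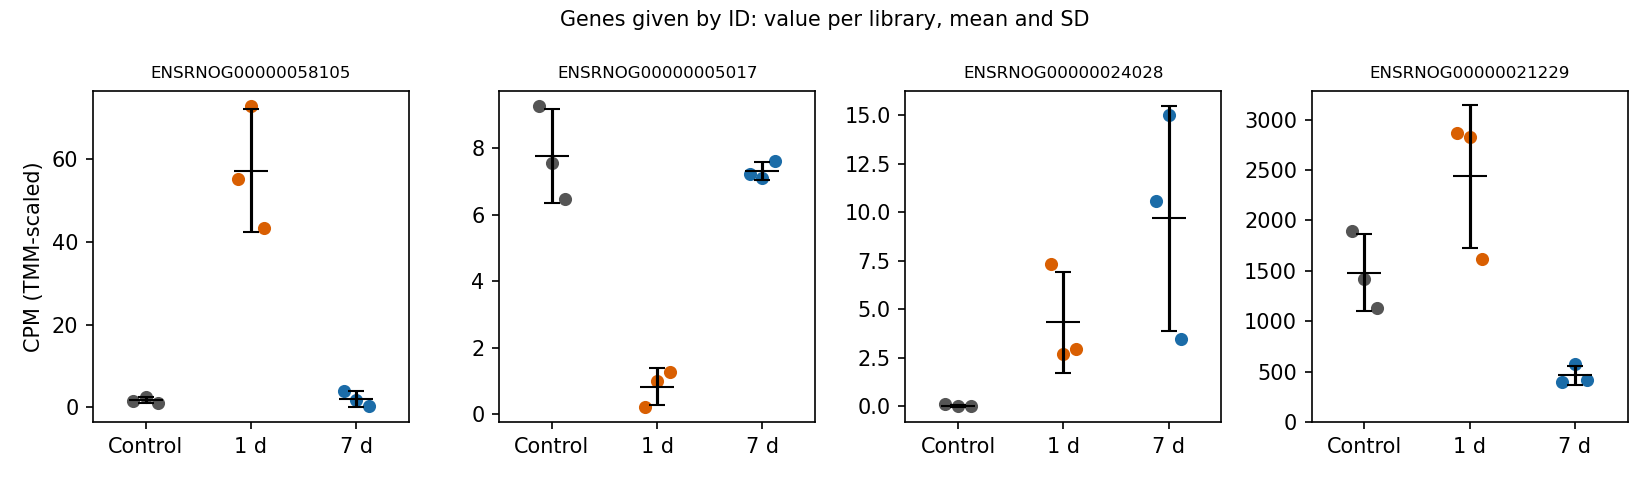
TMM-scaled CPM per library (points) with mean and SD (bars, n = 3) in Control, at 1 d and at 7 d for the 4 genes given by ID, each on its own linear scale. ENSRNOG00000058105 reached 57.2 CPM only at 1 d and ENSRNOG00000005017 fell to 0.835 CPM only at 1 d, while ENSRNOG00000024028 was at 4.34 and 9.69 CPM at the 2 times and ENSRNOG00000021229 was lowest, at 461 CPM, at 7 d.

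The third comparison tested the change between the 2 times. From 1 d to 7 d, 2320 genes rose and 2749 fell (edgeR, adjusted p below 0.05), 29.2% of the genes tested, with median log2 fold changes of 0.43 and -0.75. With library totals as the only scaling the split was 1456 higher and 3294 lower, and with upper-quartile factors rises outnumbered falls, at 2757 against 2561. The number of calls was 3299 without 1 d replicate 2 and 3071 without 7 d replicate 3. Of the genes higher at 1 d than in Control, 82.0% were called lower at 7 d than at 1 d, and of the genes lower at 1 d, 79.8% were called higher at 7 d than at 1 d; both tests use the same 1 d libraries, whose chance values push these shares up. The group that rose at 1 d, fell again and was not called at 7 d held 1612 genes, with a median log2 fold change from Control of 0.77 at 1 d and -0.16 at 7 d; the 7 d median was -0.26 without Control replicate 1 and -0.03 without Control replicate 3. The opposite group, which fell and rose again, held 1243 genes, with medians of -0.39 and 0.02. The first group held 772 genes without Control replicate 2, 737 without 1 d replicate 1 and 655 without 1 d replicate 2. The second held 579 without Control replicate 2, 572, 512 and 736 without 1 d replicates 1, 2 and 3, 764 without 7 d replicate 3 and 653 with library totals as the only scaling. A further 296 genes higher and 310 lower at 1 d were called in neither other comparison, so their course after 1 d was not resolved.

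A smaller set of genes was called at 7 d and not at 1 d. Of these, 72 were higher than Control at 7 d and also higher than at 1 d, with a median log2 fold change of 0.86 at 7 d and 0.13 at 1 d. A set of 21 was lower than Control at 7 d and lower than at 1 d, with medians of -0.69 and -0.02. A total of 10 genes were called in opposite directions, 5 up at 1 d and down at 7 d and 5 the other way round. Without Control replicate 1 these 3 sets held 183, 176 and 198 genes, and without Control replicate 2 they held 2, 1 and 0.

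**Figure D3:**
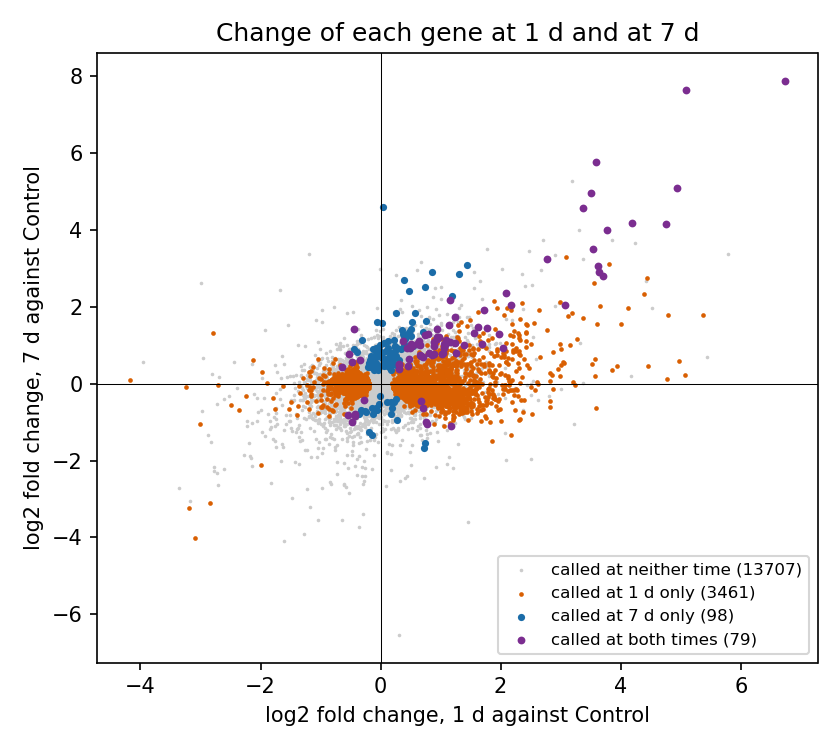
Log2 fold change against Control of each of the 17345 tested genes at 1 d (x axis) and at 7 d (y axis), coloured by the comparison in which the gene was called (edgeR, adjusted p below 0.05). The 1612 genes that rose at 1 d and fell again have a median of 0.77 on the x axis and -0.16 on the y axis (-0.03 without Control replicate 3 and -0.26 without Control replicate 1), and the 64 genes called higher at both times lie in the upper right.

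Genes changed at both times in the same direction numbered 69, of which 64 were higher and 5 lower. The 64 genes had risen by a median log2 fold change of 1.08 at 1 d and 1.12 at 7 d; between the times 9 of them rose further and 5 fell in the direct test. Independent lists of the same sizes would share 16.6 higher and 2.79 lower genes, while 50 simulations of unchanged groups against the same controls held on average only 0.7 calls at 1 d and 0.52 at 7 d, too few for their overlap, of at most 1 gene, to be set against that of the real lists. The covariance of the log2 fold changes was 0.0833, against 0.0526 ± 0.0028 (SD over simulations) with no effect, a difference of 0.0307. Their correlation across genes, which are not independent replicates, was 0.311 against 0.494 in the simulations. The 3 controls could not be split into parts of at least 2 libraries each, so part of the excess may come from the shared controls. The variance of the control mean in log2 CPM was 0.0625, above the simulated covariance of 0.0526, so the simulations may understate that part. The number of genes was 4 without Control replicate 2, 119 without Control replicate 1, 22, 30 and 29 without 1 d replicates 1, 2 and 3, 16 and 10 without 7 d replicates 1 and 2, and 151 by DESeq2.

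The direction of change at 1 d differed with transcript abundance. Among the 1000 genes with the highest mean CPM, 56 rose and 309 fell at 1 d, so 84.7% of the calls were falls. Falls made up 62.3% of the calls among the next 4000 genes (425 higher, 701 lower) and 27.0% below rank 5000 (1496 higher, 553 lower). The share among the top 1000 differed from the rest by Fisher's exact test over genes (p = 8.28e-64), which treats genes as independent although they are not; this comparison was chosen after the data were seen. It was 84.7% against 39.5% in all other genes, 67.3% against 21.9% with library totals as the only scaling, and 44.1% against 34.1% after cyclic loess normalization (138 higher and 109 lower in the top 1000), which removes trends with abundance. From 1 d to 7 d the same 1000 genes moved the other way, with 353 higher and 146 lower, and after cyclic loess normalization 216 were higher and 207 lower.

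The 20 most abundant genes took 9.59 to 12.3% of all counts in the 3 Control libraries, 8.61 to 8.72% at 1 d and 11.5 to 12.3% at 7 d. The mean fell by 1.86 percentage points from Control to 1 d and was higher by 3.17 at 7 d than at 1 d. Without Control replicate 1, whose share was 12.3%, the first difference was -0.997. The exact permutation p was 0.1 for 1 d against Control and for 7 d against 1 d, the smallest possible, and 0.3 for 7 d against Control. At 1 d 8 of these genes fell, 1 rose and 11 were not called, and after cyclic loess normalization 2 fell and 2 rose. Between 1 d and 7 d 14 of the 20 rose and 2 fell, against 7 and 2 after cyclic loess normalization.

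**Figure D4:**
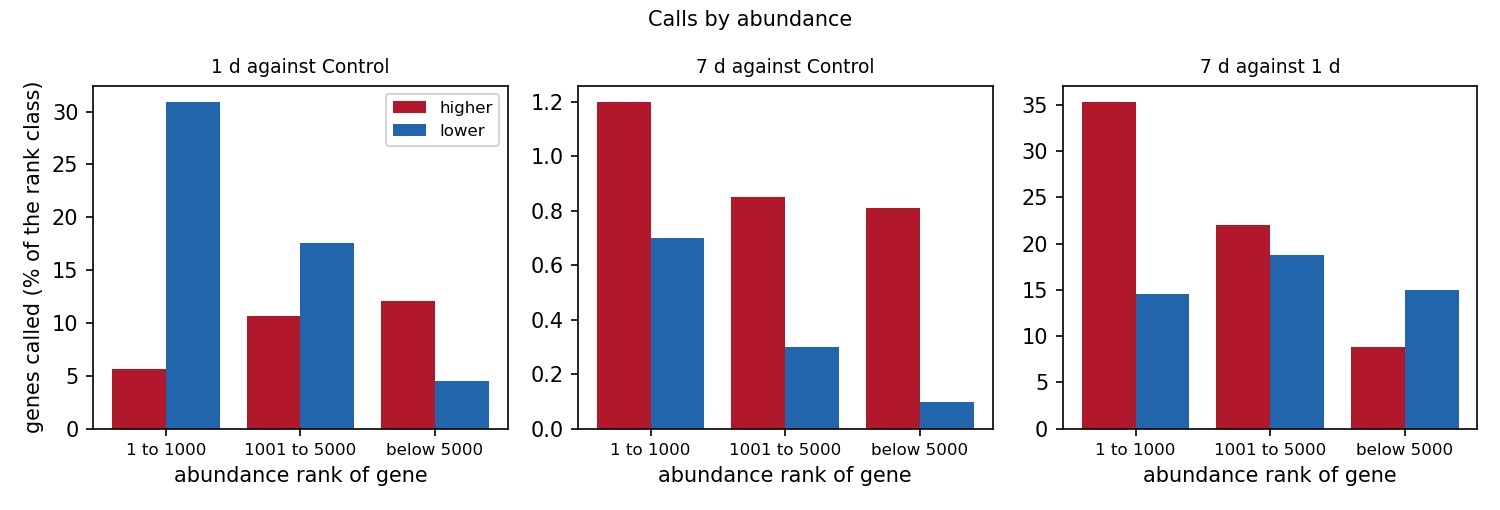
Share of tested genes called higher (red) and lower (blue) in each comparison (edgeR, adjusted p below 0.05), in percent of the genes of each abundance class by mean CPM; the y axes differ between panels. At 1 d 309 of the 1000 most abundant genes were lower and 56 higher, while below rank 5000 1496 genes were higher and 553 lower; after cyclic loess normalization 109 of the top 1000 were lower and 138 higher.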

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

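The bound for the number of calls without Control replicate 1, the test of genes at least 4-fold higher at 7 d, the comparison of calls by abundance, and all tests by thinning, cyclic loess normalization or removal of the 20 most abundant genes were chosen after the data were seen, as was the reading of which of these tests could decide. The change from Control differed between 1 d and 7 d for 5069 genes in the direct test of the difference. Of these, 2094 were called in neither comparison with Control. Among the genes given by ID, ENSRNOG00000058105 differed between the times by a log2 fold change of -4.86, ENSRNOG00000005017 by 3.15 and ENSRNOG00000021229 by -2.40.

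Far more genes were called at 1 d than at 7 d, 3540 against 177, a ratio of 20. With all libraries thinned to 13338433 counts the ratio was 19.7 (3361 and 171 genes called). The thinned ratio could not test the lower depth of the 1 d libraries as the cause. Lower depth would lower the number of calls at 1 d, so the outcome was known beforehand. The ratio moved strongly with single libraries: it was 3.58 without Control replicate 1 (2642 and 739 genes called), the lowest over all left-out libraries, and 225 without Control replicate 2, the highest. More genes were thus called at 1 d than at 7 d whichever library was left out, which argues against Control replicate 1 as the whole cause; the bound of 1.5 used for it was set after these counts were known. A transient response to the surgery is a candidate biological explanation, as a hypothesis found and tested on the same data.

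With 3 libraries against 3 only 10 splits exist, too few for a share under 0.05. The real split gave 3540 calls at 1 d against at most 2 in any other split, 177 at 7 d against at most 4, and 5069 between the times against at most 0. In each comparison 1 of the 10 splits, the real one, gave as many calls.

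Control replicate 1 differed from the other controls along the same direction in which 7 d differed from 1 d. Across genes, which are not independent, the correlation of the 2 differences was 0.305 (Spearman's rho 0.386), and the treated libraries' deviations from their own groups, set against the difference of the other groups, gave -0.12 to 0.10. Control replicate 3 departed about as far in the opposite direction (-0.30) and Control replicate 2 gave -0.06; with 3 controls these values are not independent, and which control is out of place cannot be read from them. Depth and an abundance trend are argued against as whole causes, since the correlation was 0.309 after thinning and 0.286 after cyclic loess normalization. A mislabelled library of the 7 d group stays open, because the values point both ways: with Control replicate 1 left out of the test, it lay 95.7% of the way from the other controls to the 7 d group over the 399 genes lower at 7 d and 35.6% over the 340 genes higher at 7 d, or 68.1% over both, between the bounds of 50 and 75 that had been set, and over the 29 genes at least 4-fold higher at 7 d it stood 0.39 (log2) above the other controls, against 2.30 to 3.26 in the 7 d libraries. Choosing these genes by the other controls' values pulls such shares up. Over the 29 genes the upper quartile of Control replicate 1 was 0.95, below the lowest 7 d median of 2.30. For these genes alone this met the bound against a mislabelled library, which was set after the data were seen. Dissection and state of the animals were not tested, and no biological explanation was tested because the labels give the controls no further property.

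Falls at 1 d were concentrated among abundant genes, at 84.7% of calls in the top 1000 against 39.5% in the rest. Greater power for small changes of abundant genes could not be decided by a fold minimum. Among changes of at least 1.5-fold the share was 62.1% (18 lower, 11 higher, exact 95% interval 42.3 to 79.3, taking genes as independent) against 13.8%, which met the bound set against it. However, whether this minimum made power equal in the top 1000 and the rest was not tested. The 31.3% of simulated 1.5-fold changes recovered at 1 d is a single share, not split by abundance, so it cannot show this. At 2-fold the top 1000 had 0 falls and 5 rises. Over all genes, called or not, the median log2 fold change was -0.163 in the top 1000 and 0.027 below rank 5000, values that do not depend on calls. An abundance-dependent trend between libraries stays open: cyclic loess normalization gave 44.1% against 34.1%, but it brings the medians of both classes to within 0.00103 (log2) of each other by construction, from 0.160, so it would give this outcome for a technical and a biological trend alike and these cannot be told apart; this reading of the test was made after its value, which met the bound set for a technical trend, was seen. A loss of counts from the 20 most abundant genes could not be decided as the cause by removing them. Without these 20 genes the share was 84.6% against 39.5%. Their removal shifted log2 fold changes by a median of only 0.000323, below the 0.01 under which the test was taken as void. TMM scaling thus hardly depended on these genes, and the share could scarcely have moved. A lower output of abundant transcripts after surgery also remains an untested biological alternative.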

How the results depend on the processing

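Thinning, Ensembl IDs only, removal of the 20 most abundant genes, cyclic loess normalization, other numbers of most abundant genes, all settings of the pseudo-F and of the share of falls by abundance, and leaving out libraries for the shares of counts were added after the data were seen. Where not stated otherwise below, the numbers of genes changed in each comparison and at both times stayed within 1.5 times. A minimum of 2-fold left 743 genes at 1 d, 80 at 7 d, 1110 between the times and 32 at both times, by its construction. Fits of only the compared groups, which hold fewer samples, gave 2066 at 1 d and 28 at 7 d but 5890 between the times. The cause was not tested. DESeq2 gave 514 at 7 d and 151 at both times; the cause was not tested. Leaving out a library gave 1440 to 4595 genes at 1 d, 7 to 739 at 7 d, 3071 to 6070 between the times and 4 to 119 at both times; the lowest 7 d count came without Control replicate 2, with 6 of the 177 genes still called, and the highest without Control replicate 1, with 171.

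Same-numbered replicates of different groups did not deviate together (r -0.15 to 0.04 in 9 pairs, against -0.11 to 0.19 in other pairs). Not every library correlated best with its own number. No pairing by number was thus seen, although 3 libraries per group cannot exclude a weak one. With the replicate block 2595 genes were called at 1 d, 74 at 7 d, 4319 between the times and 22 at both times.

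The uncalled 7 d change of ENSRNOG00000058105 turned to -0.41 with limma-voom, -0.46 with cyclic loess, -0.03 without Control replicate 3 and -0.81 without 7 d replicate 1, and that of ENSRNOG00000005017 to 0.060 without Control replicate 1 and 0.031 after thinning (ranges with a library left out -0.81 to 0.75 and -0.20 to 0.060); the cause was not tested. With the 2-fold minimum the share of falls in the top 1000 at 1 d was 0%, with 5 genes called. Taken over 100 genes, the share of counts in the most abundant genes rose by 3.66 percentage points from 1 d to 7 d. With a library left out the pseudo-F was 2.19 to 2.96. The scalings moved the median of all genes by -0.0861 to 0.0853 (log2). The 1.5-fold changes recovered in simulation, 26.9% at 7 d, limit what these depths and 3 libraries can show. The gene list tests were not run, because no ID was matched to a symbol.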

Other observations

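The rule for single genes did not cover the 20 most abundant genes, and the values here were chosen after they were seen. The only gene of the 20 that rose at 1 d ranked 55 in Control by mean CPM, 4 at 1 d and 45 at 7 d. It went from 1383 ± 244 to 6120 ± 85.3 CPM, a 4.43-fold increase (edgeR adjusted p = 0.000231), and stood at 1463 ± 213 CPM at 7 d (SD, n = 3 each). The gene that ranked first in all 3 groups was at 26694 ± 5882 CPM in Control, 18008 ± 637 CPM at 1 d and 28798 ± 2341 CPM at 7 d. Its log2 fold change at 1 d was -0.57 (adjusted p = 0.0197).

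IDs outside Ensembl's naming were called in 12.1% of cases at 1 d and 17.3% between the times, against 21.2% and 30.4% of Ensembl IDs; the difference was not tested.

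Fold changes at 1 d and 7 d had the same sign in 50.4% of genes, against 66.5% in simulations of unchanged groups with the same controls, and their rank correlation across genes was 0.08. The 1612 genes that rose at 1 d and fell again had a median log2 fold change of -0.16 at 7 d, which was -0.26 without Control replicate 1, -0.15 without Control replicate 2 and -0.03 without Control replicate 3. Over all genes called higher at 1 d the median difference from the mean of the controls was -0.20, 0.02 and 0.20 in Control replicates 1, 2 and 3 and -0.06, -0.05 and -0.13 in the 7 d replicates, so the 7 d libraries lay within the range of the controls.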
